A study of Limosilactobacillus reuteri subsp. rodentium with 4 samples.

How the data were processed

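Expression was measured in Limosilactobacillus (Lactobacillus) reuteri strain 100-23, a rodent gut isolate of a lactic acid bacterium. Per the labels' protocols, cells were grown anaerobically at 37 °C for 4 h in MRS medium, a rich broth for lactobacilli, made with either maltose or glucose at 2% (w/v), and were in exponential growth. Total RNA was copied into cDNA labelled with Cy3 or Cy5, and each array held RNA of a maltose culture in one colour and of a glucose culture in the other. There were 4 arrays. Replicates 1 and 2 had maltose in Cy3, and the dye-swapped arrays of replicates 1 and 2 had maltose in Cy5. The series design states that there were 2 independent biological replicates and a dye swap, so the arrays sharing a replicate number were taken as both dye orientations of one pair of cultures, called culture pair 1 and culture pair 2.

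The deposited scanner files give, per the file headers, spot brightness as intensity on a linear scale for each colour, with the mean signal, the median local background, flags for outlying, saturated and dim spots, and a processed intensity that the scanner software had background-subtracted and dye-normalised. The submitters' processing notes name Agilent Feature Extraction 9.1, whereas the file headers give version 9.5.1.1. The files also hold the software's log10 ratio of red over green. The authors' deposited value table holds log10 ratios per spot, and their scale and direction were found by setting each column against the same array's scanner values. On each array 100% of the values equalled the scanner's log10 ratio (tolerance 1e-09 on the log10 scale), with the sign turned on the arrays with maltose in Cy3, so the table gives maltose over glucose. Its column medians were 0.020 and 0.00584 for replicates 1 and 2 with maltose in Cy3 and 0.014 and 0.0151 for those with maltose in Cy5. It was used as an alternative.

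Each array carried 45220 spots, of which 1417 were controls and 41570 of the others had a locus tag of this strain. These spots represented 2143 tags through 7115 probes, a probe being one 60-base sequence of one tag. The files describe every one of these probes as unknown, so they do not pair tags with gene names. The reference gene list of assembly ASM43927v1, of another strain of the species, matched 0 of the tags. For this reason none of the 26 gene lists set before the data were examined could be matched (0 had a tested member), no list test was run, and the rule for named genes was reduced. The rule was to name the 10 largest rises and the 10 largest falls among called genes that moved the same way on all 4 arrays and had a product description, plus members of those lists. Without descriptions, only the 2 largest rises and the 2 largest falls of that kind are given, by tag.

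The main values were made from the mean signal and median local background with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8). Background was corrected with normexp at an offset of 50, and each array was normalised by loess (span 0.3) with control spots and outlier-marked spots at weight 0. The log2 ratio was turned to maltose over glucose on every array. Outlier-marked spots, 8.59% to 11.7% of an array, were left out, and saturated spots were kept. Spots of one probe were averaged, and the median over the probes of a tag was taken. A probe entered if over 0.5 of its spots were well above background in the maltose channel of all 4 arrays or in the glucose channel of all 4, which kept 6470 probes of 2090 genes, with a median of 3 probes each and 1 probe for 119 genes. Probes of 2 genes disagreed in direction by more than 0.5 on the log2 scale each way, 1 of them called, and 48 tested genes shared a probe sequence with another tag, 17 of them called. A gene not well above background in one sugar on any array has only a bound there. This applied to 6 tested genes, all dim on maltose, of which 3 were called.

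The arrays of each culture pair were averaged before the fit, so n was 2. Each gene's mean log2 ratio was tested against 0 with lmFit and eBayes (two-sided), with Benjamini-Hochberg adjustment over the 2090 genes and a threshold of 0.05. The residual degrees of freedom were 1 and the prior ones 3.74. The pairing was checked across genes: the difference between replicate numbers 1 and 2 in one dye orientation correlated with that in the other at r = 0.966. Genes are not independent replicates, and this r is given as a description. A further limma fit of the 4 arrays with a pair and a dye term tested differences between pairs and between dye orientations, against the spread between arrays only. Channel levels came from the loess values after Aquantile normalisation. Runs of consecutive tag numbers were compared with 10000 shuffles of the calls over tags. Tag numbers were used as they stand, and gene positions were not analysed here. All arrays were on 1 slide.

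The steps were tested on simulated data for the maltose over glucose comparison, with 2090 genes, 200 of them changed at the spot level, and the real spread between culture pairs reassigned among genes. Of the genes changed 4-fold 86.6% were called, of those changed 2-fold 8.96%, and of those changed 1.41-fold 0%. No unchanged gene was called (0 of 1890). The spread was added with opposite signs to the culture pairs, so it cancelled in each gene's mean. Real differences between cultures need not cancel, so this count cannot measure the rate of false calls. The simulation changed 200 genes, whereas 613 were called in the data, and the Benjamini-Hochberg cut depends on how many genes change. These rates therefore need not hold for the data. Changes were understated: a true log2 change of 2 was estimated at a median of 1.65, and one of 1 at 0.763. The number of arrays and of culture pairs limits the precision of every value. Alternatives covered the treatment of dye orientations and pairs, background correction, normalisation, the filter on dim probes, the summary over probes, thresholds, the variance model, single probes, other probes of the array, the authors' deposited table and leaving out arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.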

Results

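The data are 4 two-colour arrays that compare L. reuteri 100-23 grown on maltose with the same strain grown on glucose, from 2 independent pairs of cultures, each hybridised in both dye orientations. Maltose is a disaccharide of glucose, and the series title gives its utilisation as the subject. The median spot signal of the maltose channel was 643 and 679 on the arrays with maltose in Cy3 (replicates 1 and 2) and 829 and 721 on those with maltose in Cy5. The glucose channel had medians of 257, 172, 171 and 105 in the same order. Negative controls lay between 34.7 and 36.7 in both channels. Between 87.8% and 97.0% of the non-control spots were well above background in the maltose channel and between 91.2% and 99.1% in the glucose channel, and at most 0.107% were saturated. Gene log2 ratios of arrays with the same replicate number correlated across genes at r = 0.987 and 0.984, and those of arrays with different numbers at r = 0.806 to 0.819. The number of arrays limits the precision.

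The comparison asked which genes are expressed at another level when maltose replaces glucose as the sugar. Transcripts of 613 of 2090 tested genes (29.3%) differed between the sugars, 278 of them higher and 335 lower on maltose (limma, adjusted p under 0.05, n = 2 culture pairs). All 613 had the same sign on all 4 arrays, which is no separate support, since the calls came from these arrays. The median absolute change of the called genes was 0.95 on the log2 scale. The large changes were mostly falls: 180 called genes were at least 2-fold lower on maltose and 91 at least 2-fold higher, 75 were at least 4-fold lower and 11 at least 4-fold higher, and 31 were at least 8-fold lower and 3 at least 8-fold higher. The 8 called tags of a run of 14 consecutive tags, described below, are among both the 75 and the 31. Their maltose signal lay near the floor, and in pair 2 their log2 ratios were only -2.75 to -1.78. The other 67 of the 75 lay outside that run. Bright genes were called more often than dim ones: 285 of the brightest 697 genes were called, 225 of the middle 696 and 103 of the dimmest 697.

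The files do not pair locus tags with gene names, so the 2 largest rises and the 2 largest falls are given by tag. Lreu23DRAFT_4916 was 21.3-fold higher on maltose (log2 ratio 4.41 ± 0.52, SD, n = 2, SE 0.22, limma adjusted p = 0.000998), with 4.78 in pair 1 and 4.04 in pair 2. Its neighbour in number, Lreu23DRAFT_4917, was 11.2-fold higher (3.49 ± 0.0092, SD, n = 2, SE 0.15, limma adjusted p = 0.000998). Both belonged to a run of 4 consecutively numbered tags that all rose. Lreu23DRAFT_3489 was 54.0-fold lower on maltose (log2 ratio -5.75 ± 0.33, SD, n = 2, SE 0.18, limma adjusted p = 0.00074), with -5.99 in pair 1 and -5.52 in pair 2. Lreu23DRAFT_3490 was 50.4-fold lower (-5.65 ± 0.26, SD, n = 2, SE 0.17, limma adjusted p = 0.00074). These belonged to a run of 3 consecutive tags that all fell. All 4 genes were above background in both channels of all 4 arrays. On no array did any of them have over 0.5 of the spots saturated in every probe. That measure can miss saturation of single probes. The 3 probes of Lreu23DRAFT_4916 gave mean log2 ratios of 4.22 to 4.68 and the 6 of Lreu23DRAFT_4917 gave 3.30 to 3.74. The 3 probes of Lreu23DRAFT_3489 gave -5.84 to -5.40 and the 3 of Lreu23DRAFT_3490 gave -5.83 to -5.50.

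**Figure D1:**
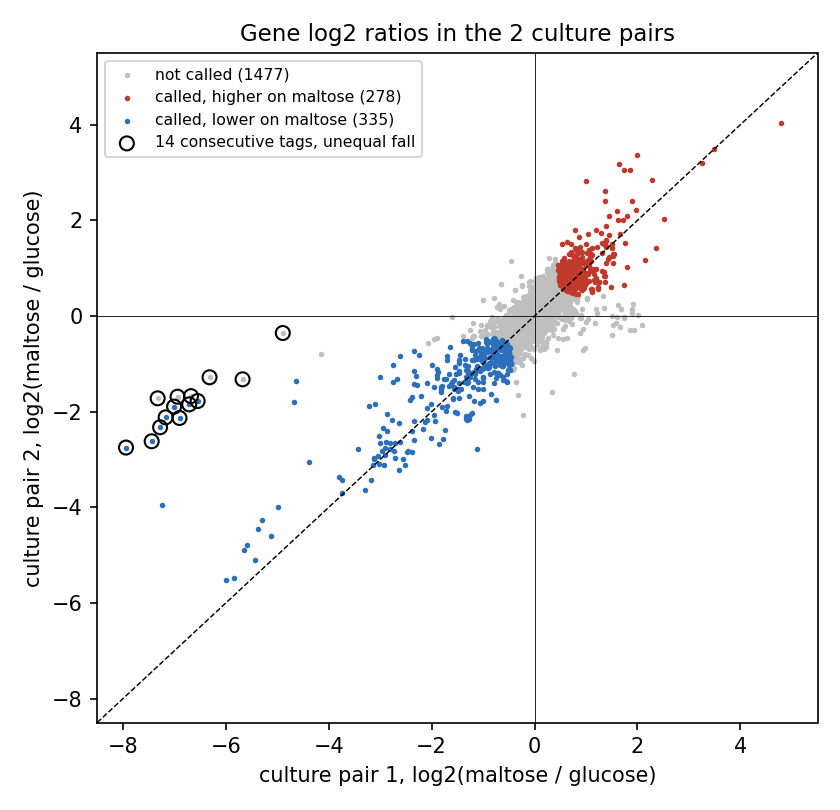
Each point is 1 of 2090 genes, with its log2 ratio of maltose over glucose in culture pair 1 on the x axis and in pair 2 on the y axis, each the mean of 2 dye orientations. Called genes are coloured (278 higher in red, 335 lower in blue), the dashed line marks equal values, and circles mark 14 consecutive tags whose median measured ratio, limited by a maltose signal near the floor, was -6.92 in pair 1 and -1.81 in pair 2.

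The culture pairs differed most in a run of 14 consecutive tags, chosen after their values were seen. Of the 14, 8 were called, with a limma adjusted p from 0.0338 to 0.0494, against 0.055 to 0.116 for the others. The median measured log2 ratio of the 14 genes was -6.92 in pair 1 and -1.81 in pair 2. Their median maltose level on the log2 scale was 5.91 in pair 1 and 6.20 in pair 2, against 5.83 for the negative controls. Of the 14 genes, 4 were above background on maltose on all 4 arrays, with levels from 6.31 to 6.88, 8 were so on 1 to 3 arrays and 2 on none. Without those 2 the medians were -6.92 and -1.81. With the maltose signal so near the floor, the measured ratios are limited by it and are not exact changes. The median glucose level was 12.9 in pair 1 and 8.19 in pair 2.

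**Figure D2:**
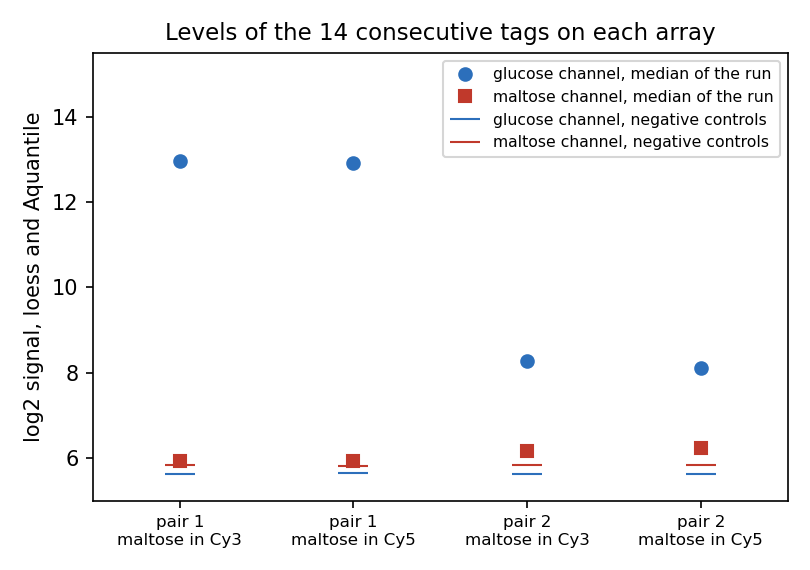
The y axis gives the log2 signal after loess and Aquantile normalisation on each of the 4 arrays, named on the x axis by culture pair and maltose dye. Points are medians over the 14 tags and bars are medians of negative controls; the glucose points stand near 12.9 on both arrays of pair 1 and near 8.19 on those of pair 2, and the maltose points lie between 5.92 and 6.24.

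Genes with consecutive tag numbers moved together. Of 2011 tested pairs of consecutive tags, 262 were called in the same direction and 40 in opposite directions. Shuffling the calls over the tags 10000 times gave a mean of 87.1 same-direction pairs and a highest value of 118, so the permutation p was 1e-04, the smallest these shuffles can give. In all, 403 called genes stood in 141 runs of at least 2 tags. The 4 runs of at least 8 tags, which held 38 genes, all rose, with median log2 ratios from 0.83 to 1.11. The longest run in which every tag was called lower held 6 tags; runs were counted over calls, so the 14 tags above, of which 8 were called, do not count as one run. With runs counted only over called tags that changed at least 4-fold, the 75 falls formed 42 separate runs and the 11 rises 7.

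**Figure D3:**
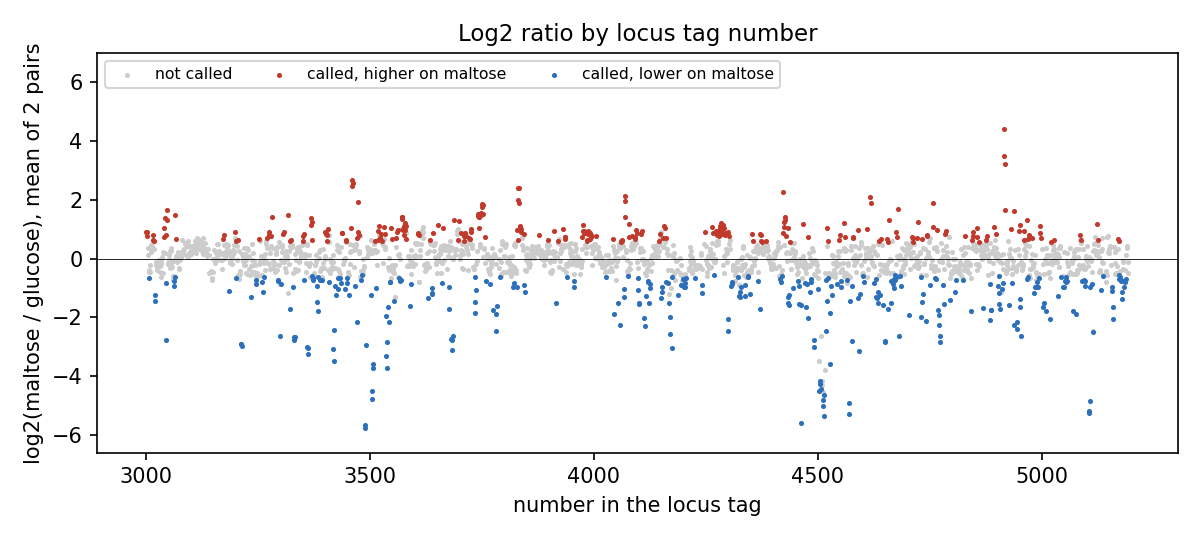
Each point is 1 of 2090 genes, placed by the number in its locus tag on the x axis and by its mean log2 ratio of maltose over glucose over 2 culture pairs on the y axis. Neighbouring tags form vertical streaks of like values, and the values reach from -5.75 to 4.41.

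The counts depend on how the arrays of one culture pair are treated. With the replicate number as a random block the 4 arrays gave 1006 called genes, 479 higher and 527 lower. The balance of directions also depended on the processing. The scanner software's processed signals gave 449 higher and 390 lower, and the values deposited by the authors 454 higher and 395 lower; both differ from the main values in background correction as well as normalisation. Median centring in place of loess gave 548 higher and 386 lower among 934 calls, moved the median of all genes to 0.17 on the log2 scale, and gave 36 of the 613 called genes the opposite sign. Median centring also narrowed the difference among large changes, with 61 genes called at least 4-fold lower and 43 at least 4-fold higher. Its calls also rest on a stronger moderation of the variances than in the main fit, so their counts do not reflect normalisation alone.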

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

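The tests of explanations for probes without a tag were chosen after the results were seen.

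The log2 ratio differed between the dye orientations for 258 of 2090 genes in the 4-array limma fit (adjusted p under 0.05), in 1 of them by at least 2-fold. The named genes Lreu23DRAFT_4916 and Lreu23DRAFT_4917 were among the 258. With maltose in Cy5 rather than Cy3, the ratio of Lreu23DRAFT_4916 changed by -0.37 (limma adjusted p = 0.0319) and that of Lreu23DRAFT_4917 by 0.60 (limma adjusted p = 2.9e-06). The change of Lreu23DRAFT_4916 rested on 1 array: its log2 ratio was 4.73 with maltose in Cy3 and 4.83 with maltose in Cy5 in pair 1, and 4.46 and 3.62 in pair 2. Each orientation is held once by each culture pair, so a dye effect shared by both pairs cancels in the mean. A deviation on 1 array does not cancel. Without the array that gave 3.62, the log2 ratio of Lreu23DRAFT_4916 was 4.62 rather than 4.41.

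Signal appeared in probes that the comparison of tagged genes does not use. Spots of RNA spike probes were well above background in 9.92% of cases in the glucose channel, against 3.11% of the negative controls. In the maltose channel the shares were 5.56% and 2.78%. Spots of the 3 resistance-marker probe sets were at 0%, 0% and 2.78%. The array also holds 283 distinct sequences with a probe number and no tag or description, and a further 3 that are shared with tagged probes. Of the 218 bright enough to test, 85 were called (limma, adjusted p under 0.05), 80 lower and 5 higher on maltose, with a largest fall of -3.72 and a largest rise of 3.29 on the log2 scale. At least 2-fold changes were 66 falls and 4 rises. With median centring 72 were called lower and 11 higher, and with the scanner software's processed signals 84 lower and 16 higher. Their median was -0.56. What these sequences represent is not given in the sources used here.

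For this fall of the untagged probes, each of the 218 tested sequences was set against the 50 tagged probes nearest in brightness. The median difference was -0.52 on the log2 scale, whereas a bias that depends on brightness alone would move both alike. The difference was -0.50 with median centring and -0.75 with the scanner software's processed signals. Matching on brightness removes any shift that depends on brightness alone, so these values repeat the brightness test. They are no separate test of normalisation. A dye effect would turn the sign between orientations, and over all 218 sequences the median difference was between -0.60 and -0.32 on the 4 arrays. A difference between the sugars that sets these sequences apart from tagged genes stays open as a hypothesis, as does a difference in RNA preparation between maltose and glucose cultures, for which no test was available.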

How the results depend on the processing

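The pairing values under other settings were chosen after seeing the data; the other alternatives were set before the data were examined. The 4 named genes kept their direction in all 19 alternatives each and their call in the 17 with a test (limma adjusted p at most 0.00323), with log2 ratios from 4.04 to 5.37 for Lreu23DRAFT_4916, from 3.32 to 4.42 for Lreu23DRAFT_4917, from -5.99 to -4.49 for Lreu23DRAFT_3489 and from -5.84 to -4.56 for Lreu23DRAFT_3490. The count of 613 calls stayed within 1.5 times in 15 of 23 alternatives, that of 278 higher genes in 11 of 17 and that of 335 lower genes in 14 of 17.

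The pairing of dye orientations stayed at r of 0.949 to 0.964 under 5 other settings. With the replicate number as a random block (correlation 0.788) there were 1006 calls, 479 higher and 527 lower, including 605 of the 613. Without a block, the 4 arrays taken as separate values gave 1412 calls, 700 higher and 712 lower, and a dye term gave 1245, 619 higher and 626 lower. These fits take arrays of one culture pair as more or fully independent and so have more degrees of freedom.

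Median centring gave 934 calls, of which 548 were higher, and shared 437 with the 613. Of its calls 58.7% were higher, and 53.5% under each of the next 2 settings, against 45.4% in the main analysis. Under median centring Lreu23DRAFT_4916 had a limma adjusted p of 1.2e-45, against 0.000998 in the main analysis. With 1 residual degree of freedom, such a value needs far more prior degrees of freedom than the main 3.74. The calls under median centring thus mix changed variance moderation with changed normalisation. The scanner software's processed signals gave 839 calls (449 higher, 390 lower), the values deposited by the authors gave 849 (454 higher, 395 lower), and both moved the median of all genes to 0.14; the causes were not tested. Thresholds gave 271 calls with at least 2-fold change, 144 at adjusted p under 0.01 and 961 under 0.10, by construction, and single probes gave 2244 of 6470 probes. Leaving out 1 array gave 578 to 750 calls, 263 to 332 higher and 315 to 418 lower. The pair then left with 1 array is assumed to vary like the other. Leaving out a whole pair leaves no test. The gene list alternatives were not run, since no tag could be matched to a list. Without the filter on dim probes 593 of 2143 genes were called, and with probes above background in both channels 689 of 1953.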

Other observations

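The tests of explanations below were chosen after the results were seen.

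The log2 ratio differed between the culture pairs for many genes. This includes ordinary variation between cultures, so it does not show that the response to the sugar itself differed. In the 4-array limma fit, 1400 of 2090 genes (67.0%) had a log2 ratio that differed between pairs beyond the spread between arrays (adjusted p under 0.05), 87 of them by at least 2-fold. The median absolute difference between pairs was 0.25, and that between dye orientations was 0.084.

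The measured log2 ratios of the run of 14 consecutive tags are limited by a maltose signal near the floor. Outside the run, the largest difference between pairs was 3.36 on the log2 scale, against a median measured difference of 4.98 within it.

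The run was picked as consecutive tags whose log2 ratio was lower in pair 1 than in pair 2 by more than 4. Each also had a limma adjusted p under 0.05 for that difference in the 4-array fit. The run's median difference between pairs was 48.0 times that between dye orientations. Since the rule demanded a large pair difference, this value cannot decide whether array or dye noise caused the unequal fall. The median glucose level differed between pairs by 4.76 and the maltose level by -0.26, so the unequal measured ratios went with the glucose level. A maltose signal at the background floor would also stay flat. These values therefore cannot decide whether the floor hid a like fall in both pairs. If maltose and glucose RNA had been mixed in pair 2, no gene should have fallen much further there than this run, yet 21 genes outside it fell by more than 3 on the log2 scale. Every tag of the run was above background on glucose on every array. The run's median glucose level in pair 2 was 8.19, against 5.62 for the negative controls. These values argue against full absence of the run from that glucose culture. A hypothesis that remains is that the glucose cultures themselves differed in the expression or partial presence of this run. With 1 glucose culture per pair that cannot be tested here.

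Of the 75 falls of at least 4-fold, 67 lay outside the run of 14 tags. The excess of large falls over rises was 6.82 falls per rise at a change of at least 4-fold. Background treatment moved part of it: normexp without an offset left 3.92 falls per rise (102 and 26 genes), so the offset is not the whole cause, and no background correction gave 86 falls and 16 rises. Normalisation may account for more of it: median centring left 1.42 (61 and 43 genes). These are counts of calls, so the changed variance moderation enters them too. Under median centring the median log2 ratio rose with brightness, from -0.52 in the dimmest 697 genes to 0.34 in the middle 696 and 0.83 in the brightest 697, whereas loess held it at -0.030, 0.061 and 0.024. Whether that trend is technical or a true difference of bright transcripts stays open.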
